A study of Mus musculus with 4 samples.

How the data were processed

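Bulk messenger RNA sequencing was compared between 2 wild-type (WT) and 2 Stra8 knockout (KO) mouse libraries. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was captured on oligo dT beads, strand-specific libraries were made with a Tecan kit and read as pairs on an Illumina sequencer. The sample labels name brain as the tissue, and the series design describes cells sorted from hippocampi for a green fluorescent reporter of the Stra8 promoter. Neither gives the sex or number of animals behind a library.

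The deposited values are raw counts of reads per gene in 1 table of the whole series, with Ensembl mouse gene identifiers. Per the submitters' processing notes, FastQC, STAR 2.6.1c, featureCounts and DESeq2 were used with the GRCm39 build. Their roles are not recorded there. The annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. The counts are whole numbers with different totals per library, from 71097417 to 82172740. Even numbers made up 72.8% to 74.3% of counts from 1 to 20, which a count of read pairs would not give, so a fragment appears to add 2 reads to a gene, and counting errors are larger than the read numbers alone would give. Intervals on single counts cover counting error only and treat reads as independent, so they are too narrow. Columns were matched to samples by name. The KO columns carry a suffix that the WT columns lack. Gene symbols were taken from a reference table that matched 52081 of the 55414 identifiers. No coordinates are given, because the reference annotation used here is of another build than the counts. It served for names, for gene order and for the X and Y classes.

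Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by genotype at its minimum count of 10 (21592 genes), libraries were scaled with TMM (factors 0.997 to 1.01), and genotype was tested with glmQLFit and glmQLFTest, without other terms. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are KO over WT. Values per library are CPM, counts scaled to the library total, computed from the counts with the scaled library size. The standard error of a log2 fold change was taken as its size over the square root of the test's F value. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over the 44 lists with at least 5 measured members. They were tested again with an estimated correlation and with fry. The lists cover neuronal, glial, vascular, blood and choroid plexus markers, signalling and metabolic pathways, meiotic genes and sex-linked genes. These lists, the design, the grouping and most of the other settings were fixed before the data were examined, as was the rule for named genes. That rule took Stra8 first, then the 12 largest rises and 12 largest falls by log2 fold change. Eligible genes were called, had a mean of at least 5 CPM, did not overlap between genotypes, and had a symbol that is not a Gm number, a Rik clone or an Ensembl identifier. For lists described, up to 4 members with the smallest p are named. Some genes that this rule takes are not reported here. The glucocorticoid-responsive and brain-region lists of the closing part were written after the first results were seen, and genes of those lists are named by choice.

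The replicate numbers in the labels are shared between the genotypes, and a fit with the number as a block was also run. Other settings fixed in advance were DESeq2 size factors, library size alone, no filter and a stricter one, DESeq2 1.42.0, limma-trend, a fold minimum of 1.5, an adjusted p under 0.1, each library left out in turn, and mitochondrial and ribosomal protein genes left out. After seeing the data, 4 were added. These were counts halved and rounded, X and Y genes left out, each genotype counted as 1 sample, and an edgeR fit with the dispersion set to 0 (quasi-Poisson).

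The procedure was tested on simulated data for KO against WT, drawn from the real means and library sizes with a variance of 2.5 times Poisson. Of 21594 simulated genes tested, 50 each were changed by 1.1-fold, 1.2-fold, 1.5-fold and 2-fold. The test called 28%, 76%, 100% and 100% of them, all in the right direction. It also called 34 unchanged genes among 186 calls (18.3%), above the nominal 5%, and 32 of the 34 had mean counts above 30000. With the dispersion set to 0, 10 of 168 calls were of unchanged genes, and with limma-trend 7 of 165, in each case 0 of them above 30000 counts. The default fit was kept because it was fixed in advance. The fit with dispersion 0 was chosen after several fits had been compared on simulated data, and it is given as an alternative. In the real libraries 142 genes above 30000 counts were called, and all 142 were also called by limma-trend and by the fit with dispersion 0. Above 30000 counts the real same-genotype pairs varied by 3.87 (WT) and 5.02 (KO) times Poisson, more than the simulated 2.5. The simulated false calls of any of these fits therefore may not carry over to the 142. In a simulation of lists, 1 list moved by 0.2 on the log2 scale was called (camera adjusted p = 3.85e-16) and 0 of 43 unmoved lists were. With an estimated correlation the moved list was not called (adjusted p = 0.683), so with 4 libraries that form of the test could miss a shift of this size.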

Results

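The data collected were 4 bulk messenger RNA sequencing libraries from mouse brain, 2 from wild-type (WT) animals and 2 from Stra8 knockout (KO) animals. Stra8 is best known as the gene through which retinoic acid starts meiosis in germ cells. The sample labels name brain as the tissue. The series design describes animals of both genotypes with a reporter in which the Stra8 promoter drives green fluorescent protein, and cells positive for it sorted from hippocampi. The stated comparison is of the transcriptomes of such cells with and without Stra8. Every library also held transcripts that mark cerebellum and pituitary, with Cbln3, Gabra6, Pcp2, Gh and Prl each at 2.65 CPM or more in all 4, so the values are described here as those of the WT and KO libraries. The values were raw read counts for 55414 genes. Total counts were 80310856 in WT library 1, 81905583 in WT library 2, 82172740 in KO library 1 and 71097417 in KO library 2. Each library detected between 28356 and 28801 genes, and mt-Co1 was the most abundant gene in all 4, with 1.55% to 1.58% of the counts.

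Stra8 itself (ENSMUSG00000029848), the targeted gene, was close to undetected in every library. It had 5 reads in WT library 1, 1 in WT library 2, 7 in KO library 1 and 4 in KO library 2. These correspond to 0.062 CPM (counts scaled to the library total; exact 95% binomial interval 0.020 to 0.145), 0.012 CPM (0.00031 to 0.068), 0.085 CPM (0.034 to 0.176) and 0.056 CPM (0.015 to 0.144). The intervals of all 4 libraries overlapped, and the gene did not pass the expression filter. Fitted without the filter, its log2 fold change was 0.92 (SE 1.37, edgeR adjusted p = 0.862). A difference in Stra8 was therefore not detectable at this depth, and the counts do not check the genotype labels, which were taken as given.

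Up to 10000 reads per gene the libraries of 1 genotype differed from each other by little more than counting noise. Between the pair of WT libraries the variance of the counts was 2.42 times the Poisson value for genes with 20 to 50 reads and 2.43 times for genes with 3000 to 10000 reads. The KO pair gave 2.56 and 2.67 times. Between genotypes the same factor rose from 2.48 to 2.68 in the lower range to 5.58 to 6.14 in the upper one. Above 30000 reads the pairs of 1 genotype reached 3.87 and 5.02 times and the pairs across genotypes 36.1 to 43.97 times. Between 72.8% and 74.3% of counts from 1 to 20 were even numbers, and between 2503 and 2590 genes per library had exactly 2 reads against 758 to 836 with exactly 1, so both mates of a read pair appear to have been counted. The labels do not say whether the 2 libraries of a genotype came from separate animals. The p-values given here therefore compare these libraries and their technical spread, not animals.

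**Figure D1:**
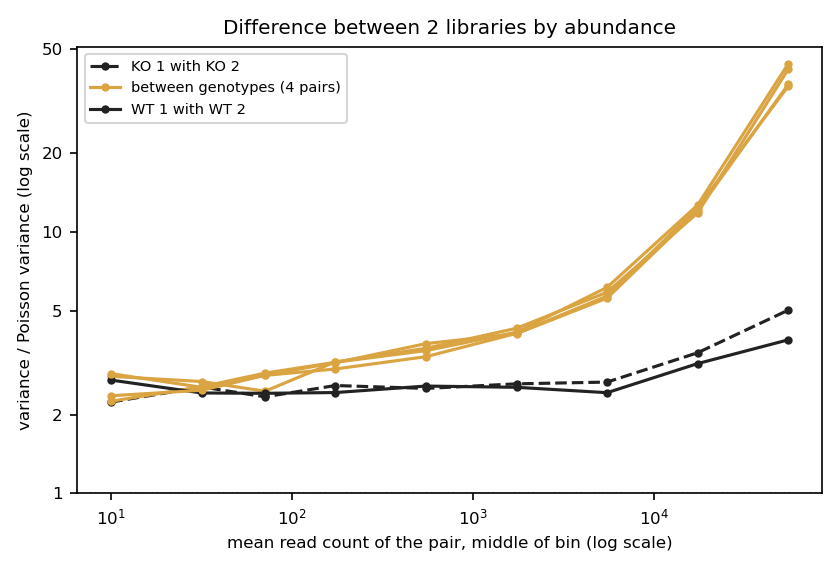
Variance of the difference between 2 libraries relative to its Poisson value (vertical, log scale) by mean read count of the genes (horizontal, log scale, middle of each bin), for each pair of libraries. The 2 same-genotype pairs stay between 2.24 and 2.71 up to 10000 reads, while the 4 pairs across genotypes rise to between 5.58 and 6.14 at 3000 to 10000 reads.

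In the KO libraries 723 genes were higher and 688 lower than in WT, of 21592 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 2 libraries per genotype). The changes were small. The median size among the 1411 called genes was 0.15 on the log2 scale, 77.5% of them changed by less than 1.2-fold, and 16 rose and 82 fell by at least 1.5-fold. The falls were larger than the rises, with a median log2 fold change of -0.18 among lower genes and 0.13 among higher genes. The genotypes did not overlap for any of the 1411 called genes. Over all tested genes 45.7% did not overlap, where chance gives 33.3%. With the libraries of each genotype summed and counted as 1 sample, a choice made after seeing the data, no test is possible. In that form 0 genes were at least 1.5-fold higher and 36 at least 1.5-fold lower among genes with a mean of 5 CPM or more.

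Several of the 12 named falls were genes known from the cerebellum. Pcp2 (ENSMUSG00000004630), a Purkinje cell gene, fell from 18.98 ± 0.58 to 7.39 ± 0.23 CPM (mean ± SD, n = 2 libraries), a log2 fold change of -1.36 (SE 0.071, edgeR adjusted p = 2.12e-12). Cbln3 (ENSMUSG00000040380), which encodes a secreted protein of cerebellar granule cells, fell from 46.6 ± 1.02 to 19.8 ± 0.23 CPM, a log2 fold change of -1.23 (SE 0.044, edgeR adjusted p = 1.79e-15). Gabra6 (ENSMUSG00000020428), the GABA-A receptor subunit of cerebellar granule cells, fell from 24.2 ± 0.021 to 10.98 ± 0.037 CPM, with a log2 fold change of -1.14 (SE 0.060). The protocadherin gene Fat2 fell by 1.17 on the log2 scale and Cnpy1 by 1.16. Slc6a5, the glycine transporter of inhibitory neurons of brainstem and spinal cord, fell by 1.103. The edgeR adjusted p of these last 3 genes lay between 9.23e-15 and 1.07e-08.

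The other 6 of the 12 named falls were 2 anterior pituitary hormone genes and 4 Y-linked genes. Gh, the growth hormone gene, fell from 34.9 ± 0.39 to 16.7 ± 0.094 CPM, a log2 fold change of -1.06 (SE 0.050, edgeR adjusted p = 2.22e-13). Prl, the prolactin gene, fell from 7.11 ± 0.63 to 3.06 ± 0.58 CPM, a log2 fold change of -1.21 (SE 0.121, edgeR adjusted p = 1.80e-07). The Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y fell, with log2 fold changes of -1.31, -1.248, -1.235 and -1.12.

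Rises were smaller. Xist (ENSMUSG00000086503), the RNA that silences 1 X chromosome in females, rose from 292 ± 7.15 to 430 ± 15.04 CPM, a log2 fold change of 0.56 (SE 0.020, edgeR adjusted p = 1.79e-15). Hprt, the X-linked purine salvage enzyme, rose from 44.2 ± 0.31 to 58.8 ± 0.50 CPM, a log2 fold change of 0.41 (SE 0.034, edgeR adjusted p = 7.41e-09). Drd1, the dopamine D1 receptor, rose from 24.3 ± 0.95 to 32.0 ± 0.40 CPM, a log2 fold change of 0.40 (SE 0.048, edgeR adjusted p = 3.33e-06). The hypothalamic peptide genes Avp (vasopressin) and Pmch (melanin-concentrating hormone) rose by 0.41 and 0.37 on the log2 scale, from 7.47 and 10.8 CPM. The muscle-type genes Myl4 and Nexn rose by 0.55 and 0.44, Sertad1 by 0.46 and Dkkl1 by 0.39. Ccn4, Cd4 and Tgfb1 rose by 0.50, 0.42 and 0.38, each from under 7 CPM. Leaving out 1 library, which leaves a lone library that is assumed to vary like those of the other genotype, ended these last 3 calls while the direction stayed. Ccn4 had a log2 fold change of 0.39 without KO library 2 (edgeR adjusted p = 0.058) and Cd4 one of 0.30 without WT library 1 (edgeR adjusted p = 0.109). Tgfb1 had 0.33 without WT library 1 and 0.28 without KO library 1 (edgeR adjusted p = 0.071 and 0.169).

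**Figure D2:**
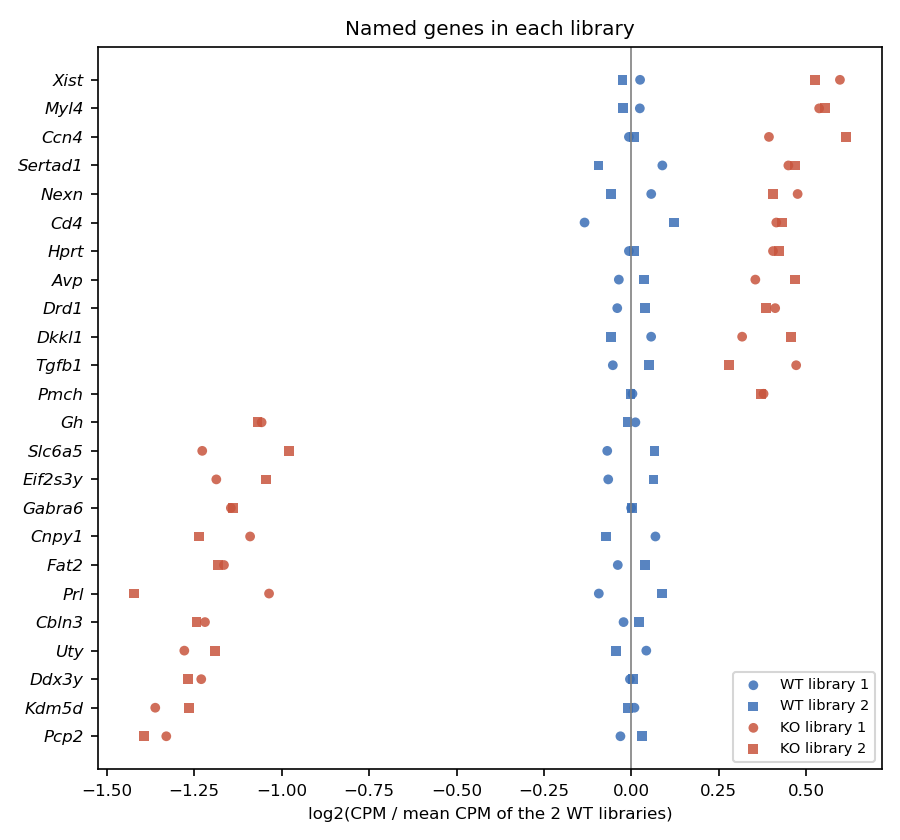
CPM of the 12 genes with the largest rise and the 12 with the largest fall in each of the 4 libraries, as log2 of the ratio to the mean of the 2 WT libraries (horizontal axis); circles are library 1 and squares library 2 of each genotype. The KO libraries lie apart from the WT libraries for all 24 genes, with fitted log2 fold changes from -1.36 for Pcp2 to 0.56 for Xist.

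The sex-linked genes were read in every library as a check of sample make-up. Ddx3y had 27.9 and 28.1 CPM in WT libraries 1 and 2, and 11.9 and 11.6 CPM in KO libraries 1 and 2. Xist had 297 and 287 CPM in the WT libraries and 440.9 and 419.7 CPM in the KO libraries. Eif2s3y had 17.9 and 19.6 CPM in WT against 8.22 and 9.07 CPM in KO, Kdm5d 16.4 and 16.2 against 6.34 and 6.77, and Uty 7.60 and 7.15 against 3.04 and 3.23. Every library thus held reads of both Xist and the Y-linked genes. Tsix, which is antisense to Xist, had 0.273, 0.622, 0.452 and 0.508 CPM in the 4 libraries in the same order. Because the strand setting of the counting is not given in the sources used here, its reads cannot be separated from those of Xist. Of the 6 sex-linked genes 1 rose and 4 fell, over all genes tested and also adjusted over the list alone.

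Of 44 gene lists fixed before the data were examined, 9 were called higher in KO and 7 lower (limma camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 44 lists). None of the 16 calls held with a correlation estimated from the libraries, where their adjusted p ranged from 0.346 to 0.470. In simulation that form also missed a list moved by 0.2 on the log2 scale (camera adjusted p = 0.683). Its adjusted p is given for each list below, and a call lost in it does not show that a list did not shift. The rotation test fry, which asks whether the genes of a list move on balance to one side, called 6 lists, 5 of them among the 16. These 5 were dentate granule cells, choroid plexus and ependyma, sex-linked genes, presynaptic vesicle release and cholesterol synthesis. The sixth was antigen presentation, with 1 of 21 members down and 0 up in both adjustments and a median of -0.16 (fry adjusted p = 0.0244, camera adjusted p = 0.065). With 1 library left out its median ranged from -0.14 (without WT library 1) to -0.064 (without WT library 2).

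Markers of dentate granule cells, the principal neurons of the dentate gyrus, were lower. Of 15 measured members 10 fell, 1 rose and 4 did not pass (12 and 1 adjusted over the list alone), with a median log2 fold change of -0.22 (camera adjusted p = 3.20e-11; adjusted p = 0.346 with an estimated correlation). Dsp, the desmosomal protein desmoplakin, fell from 15.5 to 8.63 CPM (log2 fold change -0.84, SE 0.073). Lct fell by 0.78 and the complement-like synaptic gene C1ql2 by 0.63. Prox1, the transcription factor that sets granule cell identity, fell from 56.6 to 46.8 CPM (log2 fold change -0.27, SE 0.035). In the same libraries a list of 15 cerebellar genes, written after the first results, had a similar median of -0.21, with 9 members down and 0 up. Markers of CA1 pyramidal cells were lower by a smaller amount, with 3 of 12 members down, 0 up and a median of -0.045 (4 down and 2 up adjusted over the list alone). Fibcd1 fell by 0.36 and Gpr161 by 0.29. The camera adjusted p of the CA1 list was 0.0356, and 0.432 with an estimated correlation. It was 0.058 without WT library 1 and 0.085 without KO library 2, where the median was -0.019 and -0.027, and 0.128 with a stricter expression filter. The CA3 and CA2 list was not called (camera adjusted p = 0.065), with 5 of 14 members down and 2 up.

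Choroid plexus and ependymal markers, the genes of the epithelium that makes cerebrospinal fluid, were lower. Of 16 members 6 fell, 0 rose and 10 did not pass (9 fell adjusted over the list alone), and the median was -0.36 (camera adjusted p = 4.62e-11; adjusted p = 0.346 with an estimated correlation). Ttr, which encodes the thyroid hormone carrier transthyretin, fell from 560 to 386 CPM (log2 fold change -0.54, SE 0.015, edgeR adjusted p = 1.29e-17). Kl fell from 30.0 to 20.8 CPM, Clic6 from 19.4 to 14.5 CPM and the bicarbonate transporter gene Slc4a5 from 6.63 to 3.56 CPM. Astrocyte markers were also lower, with 6 of 20 members down and 0 up, but with a median of -0.057 (10 down and 1 up adjusted over the list alone). The glutamate transporter gene Slc1a3 fell from 613 to 572 CPM and Atp1b2 from 696 to 661 CPM. For astrocytes camera gave an adjusted p of 0.000159, and 0.346 with an estimated correlation.

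Oligodendrocyte markers were higher. Of 20 members 11 rose, 2 fell and 7 did not pass (12 and 2 adjusted over the list alone), with a median of 0.074 (camera adjusted p = 5.89e-08; adjusted p = 0.346 with an estimated correlation). Ugt8a, which makes a myelin lipid, rose from 107 to 121 CPM. Mbp rose from 4840 to 5063 CPM, a call that was lost when counts were halved (edgeR adjusted p = 0.300). Enpp2, which choroid plexus also transcribes, went the other way and fell from 456 to 378 CPM. Among oligodendrocyte precursor markers 4 of 15 members rose and 0 fell, in both adjustments, with a median of 0.063. Gpr17 rose from 134 to 147 CPM and Enpp6 from 18.6 to 23.3 CPM. For the precursor list the camera adjusted p was 0.00616, 0.346 with an estimated correlation and 0.063 without WT library 1.

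The lists of presynaptic release, immediate-early genes and the respiratory chain were called higher on small shifts, and most of their members did not pass. In the same libraries sets of striatal and neocortical marker genes written after the first results had larger medians, 0.18 and 0.13 on the log2 scale, with 8 of 11 and 8 of 12 members up. In the presynaptic vesicle release list 9 of 33 members rose and 2 fell (13 and 5 adjusted over the list alone), with a median of 0.029. Stx1a, the plasma membrane syntaxin of vesicle fusion, rose from 179 to 207 CPM (log2 fold change 0.21, SE 0.020) and Syngr1 from 522 to 561 CPM. Camera gave an adjusted p of 3.44e-05, and 0.346 with an estimated correlation. Of 22 immediate-early genes, which neurons induce on activity, 7 rose and 2 fell (7 and 3 adjusted over the list alone), with a median of 0.044. Egr1 rose from 396 to 473 CPM (log2 fold change 0.26, SE 0.015), Arc from 297 to 346 CPM and Egr3 from 228 to 262 CPM, while Jun fell from 80.6 to 70.1 CPM. In camera the adjusted p was 0.00219, and 0.346 with an estimated correlation. The median of this list was 0.0059 without WT library 1 and 0.0735 without WT library 2, and the list was called in both cases. In the nuclear-encoded respiratory chain 7 of 71 members rose, among them Cox6b1, and 0 fell (11 rose adjusted over the list alone), with a median of 0.030 (camera adjusted p = 0.000250; adjusted p = 0.346 with an estimated correlation). Cox6b1 rose from 129 to 141 CPM.

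Further lists were called on small shifts. For cholesterol synthesis 2 of 22 members rose, among them Hmgcs1, and 0 fell (3 rose adjusted over the list alone), with a median of 0.041. The camera adjusted p was 0.00357, 0.346 with an estimated correlation and 0.056 without KO library 1. Hmgcs1 rose from 326 to 347 CPM. In the same libraries the medians of the oligodendrocyte, striatal and neocortical markers were 0.074, 0.18 and 0.13. Of 13 mitochondrially encoded messenger RNAs 2 rose and 0 fell in both adjustments, with a median of 0.026. Their camera adjusted p was 0.000265, 0.470 with an estimated correlation and 0.775 without WT library 1. The median was 0.0061 without WT library 1, 0.0749 without WT library 2 and 0.0441 without KO library 1. The rise of mt-Cytb from 8351 to 8650 CPM was not called by DESeq2 (adjusted p = 0.297), and its log2 fold change of 0.051 was 0.027 without WT library 1. For mt-Nd6, with a log2 fold change of 0.080, or 0.050 without WT library 2, the edgeR adjusted p was 0.378 without WT library 2 and 0.0697 without KO library 2. The microglial list had a median of 0.047 and 0 of 21 members passed in either adjustment. This list lost its call with the replicate block (camera adjusted p = 0.0631), library size alone (0.0522) and the stricter filter (0.130). It also lost it with halved counts (camera adjusted p = 0.0597) and with X and Y genes left out (0.0730). Its camera adjusted p was 0.0455, 0.367 with an estimated correlation, and between 0.0775 and 0.195 with any 1 library left out, where the median ranged from 0.0312 (without WT library 2) to 0.0654.

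The erythroid list was higher, with 5 of 8 members up and 0 down (6 up adjusted over the list alone) and a median of 0.24 (camera adjusted p = 2.97e-07; adjusted p = 0.367 with an estimated correlation). Hbb-bs rose from 110 to 132 CPM and Hba-a1 from 41.4 to 48.2 CPM. The globin genes have near-identical copies, so their separate values are uncertain.

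Inflammatory and dissociation-response genes were lower in part. Of their members, Lcn2, Nfkbia and Zfp36 also belong to lists of glucocorticoid-responsive genes written after the first results. Lcn2 and Zfp36 are in a list of 11 genes that had been noticed among the falls. Its median of -0.67, with all 11 below 0, was fixed by that choice. Nfkbia is in a list of 13 genes not inspected before their test. All 13 lay below 0 in the same libraries, with a median of -0.28. In the complement and inflammatory list 3 of 21 members fell and 0 rose (4 fell adjusted over the list alone), with a median of -0.030. Lcn2, which encodes the acute-phase protein lipocalin 2, fell from 7.19 to 3.46 CPM (log2 fold change -1.06, SE 0.107). Nfkbia, the NF-kappaB inhibitor, fell from 29.6 to 21.8 CPM. Ptgs2 had 16.4 and 13.6 CPM, with an edgeR adjusted p of 0.0899 without WT library 1. The camera adjusted p of the list was 0.0206, 0.354 with an estimated correlation, 0.0673 without WT library 1 and 0.0655 without KO library 2. The size of the median followed the libraries kept, with -0.0727 without WT library 1, -0.142 without WT library 2, -0.185 without KO library 1 and -0.0238 without KO library 2. In the tissue-dissociation list 4 of 24 members fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.10. Zfp36 fell from 7.83 to 5.26 CPM and Nfkbia and Jun fell as above, while Egr1 rose. The camera adjusted p was 0.0164, 0.354 with an estimated correlation, and between 0.0584 and 0.319 with any 1 library left out. The median was -0.0578 without WT library 2 and -0.0171 without KO library 2, and -0.0419 with a stricter expression filter (camera adjusted p = 0.0734).

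**Figure D3:**
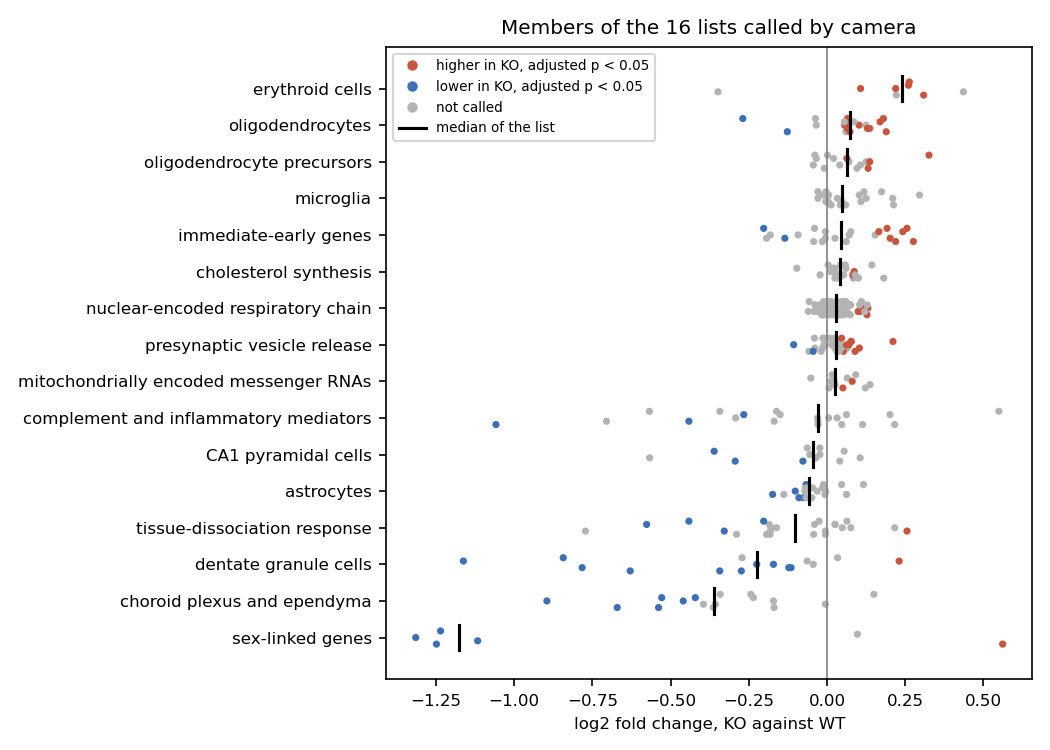
Log2 fold change, KO against WT, of each measured member of the 16 called gene lists (horizontal axis, 1 point per gene, coloured where the gene passed an adjusted p of 0.05), with the median of each list as a vertical bar. Medians run from -1.18 for the sex-linked genes to 0.24 for the erythroid list.

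The other 28 lists, antigen presentation among them, were not called by camera, with adjusted p from 0.054 to 0.981. Among 22 measured meiotic and germ-cell genes, the setting in which Stra8 is best known, 0 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.938). The gene that fell was Sycp1, with 0.794 CPM in WT and 0.348 CPM in KO, and its call was lost without WT library 1 or KO library 1 (edgeR adjusted p = 0.207 and 0.296). Of 22 retinoic acid signalling genes 2 rose and 0 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.913). The rises were the receptors Rxrg, from 13.9 to 18.0 CPM, and Rarb, from 14.8 to 17.9 CPM (log2 fold changes 0.37 and 0.28). In the same libraries 8 of 11 striatal marker genes, a list written after the first results, rose and 0 fell, with a median of 0.18. Whether the 2 receptors rose apart from such region markers was not tested. For the meiotic and retinoic acid lists the median and mean differed in sign, as they did for part of the other lists that were not called.

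Several neuronal lists that were not called held members moving both ways. Of 15 glutamatergic neuron markers 7 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.209). Neurod1 fell from 43.01 to 24.7 CPM (log2 fold change -0.80, SE 0.048). Of 36 glutamate receptor and postsynaptic density genes 8 rose and 7 fell (13 and 9 adjusted over the list alone; camera adjusted p = 0.266). Homer1 rose from 218 to 262 CPM, and the AMPA receptor subunit gene Gria1 fell from 615 to 542 CPM. Of 39 voltage-gated ion channel genes 7 rose and 9 fell (13 and 12 adjusted over the list alone; camera adjusted p = 0.543). Of 20 genes of GABA receptors and GABA handling 3 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.470), among them Gabra5, which fell from 72.1 to 61.6 CPM. In the cell cycle list 0 of 36 members passed in either adjustment, and the smallest edgeR adjusted p in it was 0.24, for Rrm2. In the list of 29 Alzheimer disease and dementia risk genes 1 rose and 2 fell in both adjustments (camera adjusted p = 0.772), and Ptk2b fell from 489 to 435 CPM.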

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

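The quasi-Poisson edgeR fit, halved counts, X and Y genes left out, and each genotype counted as 1 sample were chosen after seeing the data; the other settings were planned. The counts of 723 higher and 688 lower genes moved by over 1.5 times in 2 settings: a fold minimum of 1.5 left 16 and 82, and counting each genotype as 1 sample at 1.5-fold and 5 CPM, with no test, gave 0 and 36. Both restrict the size of change by construction. Leaving out each library in turn gave 558 to 660 higher and 506 to 618 lower genes. The DESeq2 Wald test called 531 and 480, limma-trend 732 and 695, and the quasi-Poisson fit 743 and 700. With library size alone the share of higher genes among calls was 42.1% against 51.2%. Among the 1411 called genes, none that was tested changed sign in any of the 15 settings that refit the genes.

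The 9 higher and 7 lower lists became 0 and 0 with an estimated correlation and 2 and 4 with fry. Fry asks another question. The estimated correlations of the called lists ran from -0.174 (sex-linked genes) to 0.684 (erythroid cells). Some that lost their call lay below the preset 0.01, among them astrocytes (-0.0497) and presynaptic vesicle release (-0.015). The simulated list of independently drawn genes, which had been moved by 0.2, lost its call as well (camera adjusted p = 0.683). A call lost in this form is therefore not evidence that a list did not shift. These values argue against correlation between genes as the cause for the lists below 0.01, and the cause was not tested further. Leaving out 1 library gave 6 to 8 higher and 4 to 6 lower lists. Over named genes and their settings, 2686 results were the same, 94 lost their call, 65 gained one and 0 reversed. Over lists, 556 were the same, 49 lost a call and 6 gained one. With the replicate number as a block, 818 genes were higher and 772 lower, with 8 and 7 lists. The libraries numbered 1 did not deviate together (correlation across genes 0.0157), so the samples share only a number. Depth limits Stra8, with 17 reads in all, and genes changed by 1.1-fold, of which 28% were called in simulation.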

Other observations

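The tests of repeat libraries, of Xist and Ddx3y in each library, of sex-linked transcription, of a hippocampal origin, of an effect within cells and of other splits were chosen after the result was seen; the tests on held-out lists, GC content and genes flanking Stra8 were chosen before it. Genes that glucocorticoids induce were lower in the KO libraries. The group was noticed among the falls, where 11 of its genes had been seen, Plin4 (log2 fold change -1.06), Sgk1 (-0.54) and Tsc22d3 (-0.39) among them. It was then tested on 13 other responsive genes, 2 of which, Nfkbia and Cdkn1a, were also in lists fixed earlier. All 13 had a log2 fold change below 0, 10 fell at the threshold and 3 did not pass (11 fell adjusted over the list alone), and their median was -0.28, below each of 10000 random lists matched on expression. Fkbp5, a co-chaperone of the glucocorticoid receptor, fell from 61.2 to 46.2 CPM, Zbtb16 from 81.3 to 64.6 CPM and the metallothionein gene Mt2 from 79.8 to 62.7 CPM. Per1 and Klf9 had fold changes of -0.033 and -0.027 and did not pass. Without Nfkbia and Cdkn1a the median was also -0.28. This is consistent with lower glucocorticoid-responsive transcription in the KO RNA (-0.2771). The 2 libraries of a genotype may come from 1 RNA pool. A difference in handling or time of collection therefore cannot be separated from genotype.

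Lists of genes that mark brain regions outside the hippocampus were tested in the same way. Of 11 striatal genes 8 rose and 0 fell (9 and 1 adjusted over the list alone, the fall being Lrrc10b), with a median log2 fold change of 0.18. Pde10a rose from 213 to 247 CPM and Ppp1r1b from 226 to 255 CPM. Of 12 neocortical genes, 4 of which earlier lists also held, 8 rose and 1 fell in both adjustments (median 0.13). Of 9 thalamic genes, 2 of them in earlier lists, 3 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.13), and of 11 hypothalamic genes 0 passed (median 0.11, at percentile 97.1 of random lists). The neocortical, striatal and thalamic medians lay above at least 99.99% of random lists, which ignore correlation between genes. With an estimated correlation the camera adjusted p was 0.0461 for the striatal and 0.0468 for the neocortical list. It was 0.110 for the thalamic and 0.0631 for the brainstem and spinal cord list, so these 2 were not called in that form. These values were adjusted over the added lists alone, among them the glucocorticoid genes already seen in these data. They cannot be set beside those adjusted over the 44 lists. All 15 measured brainstem and spinal cord genes had values below 0 (median -0.53), though only Tph2 and Slc6a2 passed, in both adjustments. The median expression of this list was 0.76 CPM in WT and 0.33 CPM in KO, so many of its members lay at low counts. Of 2 measured pituitary genes 0 passed over all genes tested and Cga fell adjusted over the list alone (median -0.46).

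The first pattern weighed is the likeness of libraries within a genotype. If both libraries of a genotype were made from 1 pool of RNA, their variance over Poisson would be flat with abundance. The ratio of the factor at 3000 to 10000 reads to that at 20 to 50 reads was at most 1.04 over both pairs, against 2.19 to 2.40 between genotypes. Above that range the same-genotype factors did rise, to 3.14 (WT) and 3.45 (KO) at 10000 to 30000 reads. Above 30000 reads they were 3.87 and 5.02, against 36.1 to 43.97 between genotypes. Up to 10000 reads the pairs thus varied as 1 pool per genotype would, a hypothesis drawn from these data. The rise above it was not explained, so separate pools stay open, and no biological explanation was tested. A library from 1 animal is argued against by both Xist and Y-linked reads in every library, with at least 11.6 CPM of Ddx3y.

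The second is the opposite shift of Xist and the Y-linked genes. The 4 Y-linked genes shared 1 fold change within error, with a weighted mean log2 value of -1.23 (SE 0.036). A smaller share of male cells in the KO RNA may explain this, and would need female shares of 54.7% in WT and 80.7% in KO if levels scale with cell share. Genes that escape X inactivation had a median of 0.05863, with 4 of 4 above 0 but at percentile 94.0 of random lists, short of the bound of 95 set before. An effect of Stra8 loss on sex-linked transcription (-1.23) and this difference in sex mix cannot be told apart, because no library of known sex is at hand.

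The third is the fall of cerebellar and pituitary genes. An origin of all RNA in the hippocampus is argued against by Cbln3, Gabra6, Pcp2, Gh and Prl, the lowest of which had 2.65 CPM in its lowest library, while RNA of whole brain, which the tissue label would allow, was not tested. A trend with GC content or transcript length is also argued against, since 100% of the median of 15 cerebellar genes, 1 of them (Pvalb) also in an earlier list, was kept after its removal. Different shares of brain regions between the pools may explain the fall. The described dissection and sort would remove such cells, but Cbln3, Gabra6, Pcp2, Gh and Prl were present in all 4 libraries. The description therefore does not count against different shares. The median of the 15 cerebellar genes was -0.2121, below all random lists, with 12 of 15 below 0 and -0.19 without Pvalb. It missed the bound of -0.3 set before. Different region shares and an effect of Stra8 loss within cells stay open and cannot be told apart, since neither the dissection behind each library nor separate pools are known. At 3000 to 10000 reads 0 of the 2 same-genotype pairs varied as separate pools would, while above that range both varied more.

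Of the 40 tested genes nearest to Stra8, 2 were called, where 2.61 were expected (exact one-sided hypergeometric p = 0.746), so no excess of calls was seen there. The 2 were Ptn (log2 fold change 0.16, edgeR adjusted p = 6.78e-07) and D630045J12Rik (0.086, edgeR adjusted p = 0.0442). With so few calls expected, the test could miss an effect on a few neighbours. It does not decide whether donor-strain DNA around the targeted allele was a source of calls. Of the 3 splits of the 4 libraries into pairs, only the split by genotype (1 of 3) called any genes with edgeR, 1411 against at most 0 in the others, where 353 and 411 genes had an unadjusted p under 0.05 and no other tool was run. With 3 splits no share under 0.05 is possible. The other splits put 1 WT and 1 KO library in each group, so the genotype difference enters their spread within groups. Their lack of calls is thus largely built in, and no conclusion is drawn from it.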
